A study of Mus musculus with 2 samples.

How the data were processed

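RNA from 2 pools of sorted pancreatic cells was labelled with biotin and hybridised to Affymetrix GeneChip Mouse Gene 1.0 ST arrays, 1 array per pool, per the labels' protocols. The deposited values are log2 probe set values that the authors made with RMA in the oligo package, per the submitters' processing notes; the versions, the annotation and the level of summarisation are not given in the sources used here. RMA subtracts a modelled background, gives the arrays a common distribution of probe intensities and summarises the probes of a set by median polish, so a global difference in RNA content between the pools cannot be seen in these values. The values ran from 1.39 to 13.6 in the control array and from 1.15 to 13.5 in the transformed array, the range of log2 array values, and their sorted values differed by at most 0.26. Of the 35556 probe sets, 817 held identical values on both arrays. The array files themselves were not used here, so detection above background, probe-level signals and array quality were not assessed. The number of arrays limits the precision.

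Probe sets were named through a platform annotation table. Of all probe sets, 21789 had 1 gene symbol, 1621 had several and 12146 had none; only the first kind was used for genes. Entrez identifiers matched 21698 of the named probe sets to the RefSeq annotation of GRCm38.p6, which was used for current symbols, gene biotypes and gene span (the genomic length of the gene), and 91 kept the symbol of the table. No genome build is named for the deposited values, so no coordinates are given. For the 999 of 19938 genes that had more than 1 probe set, the probe set with the highest mean of the 2 values was kept. Across 665 genes with 2 probe sets above the median signal, the differences of the first and second probe set correlated with a Pearson r of 0.518 and a Spearman rho of 0.525 across genes, and the standard deviation between them was 0.29; this measures agreement between probe sets, not between samples. Of 21 such genes past 2-fold, 19 had a second probe set with the same direction and 8 a second probe set also past 2-fold.

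A difference is the log2 value of the CD44-positive transformed array minus that of the CD44-negative control array, with the groups taken from the labels. The design left no residual degrees of freedom, so no test across genes was made and genes were taken by a fixed size, an absolute log2 difference of at least 1. A gene counted only if the higher of its 2 values lay above the median of all probe sets on that array (the expression floor), which 57.9% of the genes did. The gene lists, the floor, the thresholds and the rule for named genes were fixed before the data were examined. That rule takes the 15 protein-coding genes with the largest positive and the 15 with the largest negative difference past the floor, leaving out predicted genes and olfactory and vomeronasal receptors; Cd44, Krt19, Kras and Fbxw7; and up to 4 members of each list with the largest absolute difference past the floor. Genes named outside it are said to be so.

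The 35 lists covered 11 cell types (duct, acinar, islet, myeloid, lymphoid, fibroblast and stellate, endothelial, erythroid, mesothelial, neural and glial, adipocyte) and 24 programmes, pathways and protein complexes. Of 803 list symbols, 64 had no probe set with a single gene name and 3 were matched through an older symbol; Cd44 was left out of every list. The median difference of a list was given as its percentile among the medians of 10000 random lists drawn from all named genes, with the same number of genes in each of 20 bins of mean value. A list was said to stand apart in the upper or the lower 2.5% of random lists. The procedure was tested on simulated data in which the differences of the 19938 genes were shuffled within bins. Of 50 genes given a log2 shift of 1.5, 98.0% passed 2-fold, and of 50 given a shift of -1.5, 96.0% did. Of 11344 unshifted genes past the floor, 1.90% did. These genes carry the observed differences in shuffled order, so this share is no rate of false calls. Of 100 unshifted lists of 25 genes, 3 fell outside the range of 1000 random lists. Of 100 lists shifted by 0.3, 93 lay above it. These lists held random genes, so they do not cover lists whose genes vary together.

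Alternatives were no floor and a floor at the 75th percentile, centring of each array on its median, removal of the dependence of the difference on signal (lowess with a fraction of 0.3), repeated quantile normalization, the mean over probe sets of a gene, removal of genes with several probe sets, list members past the floor only, the mean in place of the median, and random lists without matching. For list medians, a shift was counted when it exceeded the standard deviation of the medians of random lists. Random lists matched also on gene span (10 bins of mean value and 5 of span), and protein-coding genes only, were added after seeing the data. Leaving out replicates was not possible. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures used matplotlib 3.10.9.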

Results

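Gene expression was measured in 2 pools of yellow fluorescent protein (YFP)-positive cells sorted from the pancreases of 15 mice. The mice carried an activatable oncogenic Kras allele, floxed alleles of Fbw7 (gene symbol Fbxw7, the substrate receptor of a ubiquitin ligase), a YFP reporter and a tamoxifen-inducible Cre driven by the promoter of keratin 19, a keratin of duct epithelium. They were 8 weeks old, received 2 injections of tamoxifen and were killed 2 weeks later. YFP-positive cells were divided by the surface protein CD44 into a CD44-negative pool, labelled control, and a CD44-positive pool, labelled transformed. Each pool was hybridised to 1 mouse gene array, so the comparison asks how the transcripts of the transformed cells differed from those of YFP-positive cells that the submitters called non-transformed. With 1 array per group there was no replicate spread, no p-value and no error on any difference; all values below are log2 probe set values, and all differences are transformed minus control in these 2 arrays. The control array had a median of 5.23 over its 35556 probe sets and the transformed array 5.13, and the 2 arrays correlated with a Pearson r of 0.981 across the 19938 named genes, which are not independent replicates.

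Cd44, the gene used for the sort, was 3.81-fold higher in the transformed array, with values of 6.83 in the control and 8.76 in the transformed pool. This difference follows the labels and was set by the gate. Krt19, whose promoter drives the Cre, differed by 0.09 and was 10.09 in the transformed pool; with the dependence on signal removed the difference was -0.11. Fbxw7 was 6.09 in the control and 5.60 in the transformed pool, a difference of -0.49, and its other probe set differed by -0.38. Both pools were YFP-positive, so neither array measures Fbxw7 in cells without Cre activity, and whether its probe sets lie in the floxed part was not determined here. Kras had no probe set with a single gene name and was not analysed here.

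Among the 11544 genes past the expression floor, 218 were at least 2-fold higher and 42 at least 2-fold lower in the transformed pool, and 8 were at least 4-fold higher and 3 at least 4-fold lower. The lower count was 83 with no floor and 17 with the floor at the 75th percentile. Mcpt2, a mast cell chymase, had a value of 2.83 in the control and 6.79 in the transformed pool, and its relative Mcpt1 had values of 3.65 and 5.85. Where the lower value of a gene lay under the median of its array, as here, it was not shown to be above background. Both values are then given, control first, and no fold. The counts past 2-fold and 4-fold include such genes, and differences of list members are given for them too. The 2 proteases have similar sequences, and signal shared between their probe sets cannot be separated. H2ac4, a replication-dependent histone, had values of 4.50 and 6.80 and belongs to a family of near-identical genes. Sema3a, a secreted axon guidance protein, was 4.33-fold higher. Ndufa4l2, a hypoxia-induced mitochondrial protein, was 4.31-fold higher. Tmem45a was 4.08-fold higher, Lcn2, the secreted siderophore-binding protein lipocalin 2, 3.69-fold and Cyp7b1, an oxysterol hydroxylase, 3.63-fold. S100a14, an epithelial calcium-binding protein, had values of 4.53 and 6.59, and Tnc, the matrix protein tenascin C, of 4.73 and 6.73. Fam78b had values of 4.61 and 6.57 and Trim9 of 4.69 and 6.53. Aadac had values of 3.35 and 5.31 and Sptssb, a subunit of serine palmitoyltransferase, of 3.59 and 5.44.

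Ctrb1, the digestive protease chymotrypsinogen B, was 8.75 in the control and 6.83 in the transformed pool, 3.77-fold lower. Try5, a trypsinogen with near-identical copies, was 2.31-fold lower. Cpb1 (carboxypeptidase B) had values of 6.25 and 4.61, Sycn (syncollin, of zymogen granules) of 6.18 and 4.73, and Reg2, a regenerating protein of the pancreas, of 5.72 and 4.02. The largest negative difference among protein-coding genes was in the kinetochore gene Cenpw, at 4.45-fold lower. The other 2 genes at least 4-fold lower were the microRNA genes Mir302b (6.32 in the control and 2.51 in the transformed pool) and Mir154 (6.27 and 3.04), named after their values were seen. Car5b and Trim12c were 3.10-fold and 3.01-fold lower. Hoxc8 had values of 6.08 and 4.75, Cacnb2 of 5.89 and 4.60 and Defb30 of 5.78 and 4.56. Chd7, Syne2 and Arfgef2, at 3.13-fold, 2.49-fold and 2.48-fold lower in their brightest probe sets, and Set, with values of 5.67 and 4.45, depended on that choice of probe set: averaged over all probe sets of each gene the differences were -0.09, -0.48, -0.49 and -0.61.

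**Figure D1:**
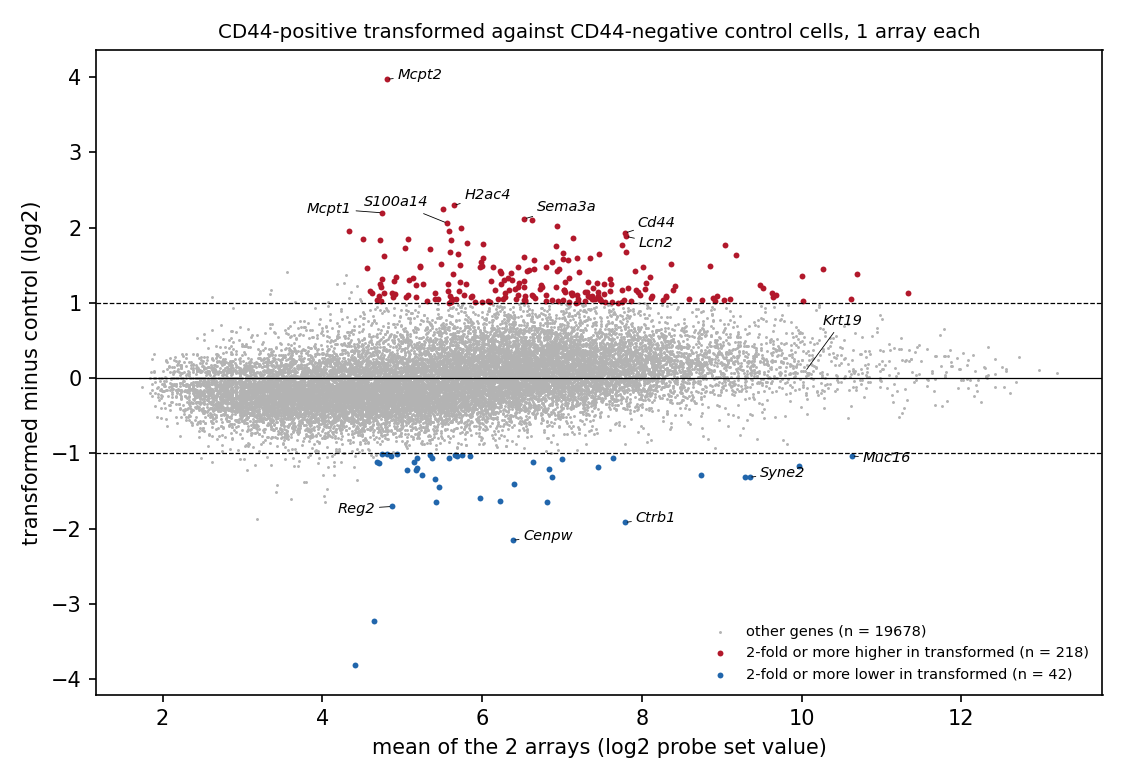
Difference between the 2 arrays (transformed minus control, log2) against the mean of the 2 log2 probe set values, 1 point per gene. Red and blue points are the 218 genes at least 2-fold higher and the 42 at least 2-fold lower among genes past the expression floor, with dashed lines at a difference of 1 and -1, and dim genes lie mostly below 0 and bright genes mostly above it (medians of -0.18 and 0.17 in the outer quartiles).

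Differences depended on signal. The median difference was -0.18 among the named genes of lowest signal and 0.17 among those of highest signal, taken below the lower and above the upper quartile of the mean value. Each of the 35 gene lists fixed before the data were examined was set against 10000 random lists of the same size matched on mean value, and its median was given a percentile among them. This percentile describes these 2 arrays and is not a test between conditions. List members are counted as past 2-fold where they were also past the expression floor. The medians of 8 lists lay in the upper 2.5% of random lists and those of 6 lists in the lower 2.5%. By chance 1.75 lists would lie outside this range if genes varied independently, which genes of 1 pathway or cell type need not do. Without matching on mean value, the ductal, fibroblast, MAPK, junction, actomyosin, NF-kB, stem cell and ribosomal protein lists also lay in the upper 2.5%. Of the list genes, 19 of the 718 genes belong to more than 1 list.

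The medians of the mitosis and DNA replication lists lay above their random ranges. Of 27 measured mitosis genes, 25 had a positive difference and 1 passed 2-fold, with a median of 0.44, above all random lists. Bub1, a spindle checkpoint kinase, was 2.01-fold higher, and Cdca8 (borealin), Ttk and Plk1, mitotic regulators, differed by 1.00, 0.95 and 0.92. Bub1 differed by 0.99 with the signal trend removed and 0.98 after repeated quantile normalization, under 2-fold. Of 29 DNA replication genes, 25 had a positive difference, none past 2-fold, with a median of 0.31 (percentile 99.9). Gins2, a subunit of the replicative helicase, and Tk1, thymidine kinase, differed by 0.99 and 0.98, and Mcm6 and Prim1 by 0.65 and 0.62.

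The list of transcripts whose proteins are known FBW7 substrates had a median of 0.34 (percentile 99.2), with 16 of 20 members positive and 1 past 2-fold. That member was Myc, a growth-promoting transcription factor, at 7.38 in the control and 8.53 in the transformed pool, 2.22-fold higher, and it differed by 0.97 with the signal trend removed. Cebpd, Ccne2 (cyclin E2) and Sox9, a ductal progenitor transcription factor, differed by 0.98, 0.94 and 0.72. MYC targets had a median of 0.32 (percentile 99.0), with 24 of 29 positive and none past 2-fold. Nop56 and Wdr43, of ribosome assembly, differed by 0.73 and 0.71, Srm (spermidine synthase) by 0.61 and Dctpp1 by 0.59. After removal of the signal trend these 2 lists had medians of 0.16 and 0.13 at percentiles 96.27 and 96.55, inside the random range. FBW7 substrates also lay inside it after repeated quantile normalization (97.35), and MYC targets with the mean (95.59) and with matching on gene span (96.15).

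The medians of the oxidative phosphorylation and the hypoxia and glycolysis lists lay above their random ranges. Oxidative phosphorylation genes had a median of 0.40 (percentile 99.9), with 28 of 29 positive, and a median of 0.20 once the signal trend was removed. Cyc1 (cytochrome c1) differed by 1.00, or 0.84 without the trend, and Cox4i1, Cox5a and Sdhd differed by 0.79, 0.70 and 0.63. Hypoxia and glycolysis genes had a median of 0.35 (percentile 99.7), with 21 of 23 positive and 2 past 2-fold. These were Bnip3, a hypoxia-induced mitophagy receptor, at 2.17-fold higher and Aldoa (aldolase A) at 2.04-fold higher; Pgam1 and the lactate exporter Slc16a3 differed by 0.85 and 0.79. The other probe set of Bnip3 differed by 0.62, and over all its probe sets Bnip3 differed by 0.87, under 2-fold. With the signal trend removed Bnip3 and Aldoa differed by 0.96 and 0.82, also under 2-fold. Without genes of several probe sets the list lay at percentile 97.47, inside the random range. Cytosolic ribosomal protein genes, with a median of 0.23, or 0.031 without the trend, lay inside their random range (percentile 69.2).

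Genes of pancreatic intraepithelial neoplasia and gastric mucous cells included 6 of 29 members past 2-fold, all higher in the transformed pool. Beside Lcn2, Ctse, a gastric aspartic protease, was 3.36-fold higher, Mmp7 (matrilysin) had values of 5.12 and 6.90, and Agr2, a disulfide isomerase of mucous cells, of 4.17 and 5.90. The remaining 2, named after their values were seen, were the mucus peptide Tff2 at 3.20-fold and the mucin Muc1 at 2.25-fold. The list median was 0.18 (percentile 99.8), its mean 0.42, and 8 members had a negative difference. With the 12 members under the expression floor left out, the percentile was 96.38, and with the signal trend removed the median was 0.27. In the list of secreted injury proteins, which shares Lcn2 and Reg1 with other lists, Lcn2 and Hp (haptoglobin, 2.04-fold, with a difference of 0.83 without the signal trend) were higher and Reg2 was lower, and the median of 0.09 lay inside the random range (percentile 92.2). The list lay in the upper 2.5% with its mean (percentile 98.08), with the signal trend removed (98.88, median 0.21) and after repeated quantile normalization (98.85), and its median was 0.38 with members under the floor left out.

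Duct epithelial genes were measured for 22 members, of which 15 had a positive difference and 1 passed 2-fold, with a median of 0.20 (percentile 90.9, and 97.50 without genes of several probe sets). Epcam, an epithelial adhesion protein, was 5.75 in the control and 6.92 in the transformed pool, 2.25-fold higher, and Cldn7, Krt8 and Prom1 differed by 0.91, 0.87 and 0.86. Junction and polarity genes had a median of 0.12 (percentile 87.7), with Cdh1 (E-cadherin) and Dsg2 at 0.93 and 0.74 and Pard6b at -0.63. Ductal ion transport genes had a median of 0.04 (percentile 62.1). Within that list the potassium channel Kcnma1 was 2.46-fold higher in its brightest probe set, a log2 difference of 1.30. Its other probe set differed by -0.59, and the difference over all its probe sets was 0.35. Car4, a carbonic anhydrase, differed by -0.92. Aqp1 and Kcnn4 differed by 0.89 and 0.62. With the signal trend removed, the ductal and junction medians were 0.11 and 0.045. In the same arrays the mesothelial list, markers of another epithelium, had a median of -0.39.

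The epithelial-mesenchymal transition list had the largest median, 0.58, above all random lists, with 19 of 23 members positive and 3 past 2-fold. Beside Tnc, Cdh2 (N-cadherin) was 2.20-fold higher and the mesenchymal transcription factor Prrx1 2.18-fold higher, and Thbs1 differed by 0.85. Prrx1 differed by 0.99 with the signal trend removed, and Prrx1 and Cdh2 by 0.98 and 0.9967 after repeated quantile normalization, under 2-fold. Fibroblast and stellate cell markers, which share the mesenchymal character of this list, had a median of 0.24 (percentile 93.9) and 3 of 24 members past 2-fold. These were Des (desmin) at 2.80-fold, Acta2 (smooth muscle actin) at 2.37-fold and Postn (periostin) at 2.24-fold, while Thy1 differed by 0.67. Their mean of 0.37 lay at percentile 99.88 among means of random lists, and their median was 0.049 once the signal trend was removed. On each array 9 of the 24 markers lay above the 95th percentile of all probe sets, as did 5 of 22 duct markers. Mesenchymal transcripts were thus bright in both pools, but values of different probe sets depend on their probes and give no share of cells.

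The medians of the acinar, lymphoid and mesothelial lists lay below their random ranges. Of 27 acinar genes, 23 had a negative difference and 4 passed 2-fold (Ctrb1, Cpb1, Sycn and Try5); the median was -0.50, below all random lists. The exception past 2-fold was Gatm, which many tissues express, at 1.14 and named after its value was seen. All 16 lymphoid genes had a negative difference, none past 2-fold, with a median of -0.65, below all random lists, but 11 of them lay under the expression floor. Cd79b and Cd247, receptor chains of B and T cells, differed by -0.83 and -0.79, and Cd3d and Prf1 by -0.73 and -0.38. Of 10 mesothelial genes, 9 had a negative difference, with a median of -0.39, below all random lists, and of -0.58 once the signal trend was removed. Muc16, a surface mucin of mesothelium, was 2.05-fold lower, and Rspo1, Lrrn4 and Gpm6a differed by -0.60, -0.52 and -0.47. Mesothelium is known to express keratin 19, and whether the YFP-positive pools held mesothelial cells was not determined.

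The medians of the other cell type lists lay inside their random ranges. Myeloid markers had a median of -0.15 (percentile 7.81), but lay at percentile 1.68, in the lower 2.5%, with members under the floor left out. They included Ptprc and Laptm5 at -0.79 and -0.49 and Cd68 and S100a9 at 0.52 and 0.51. Endothelial markers had a median of -0.01 (percentile 78.1), with Flt1 and Ramp2 at 0.70 and 0.67. Islet markers had a median of -0.10 (percentile 71.3), and Ppy and Pyy differed by -0.21 and 0.21. The islet and endothelial medians turned positive, to 0.069 and 0.089, once the signal trend was removed. Erythroid markers (6 measured) had a median of -0.20 (percentile 23.0), adipocyte markers -0.21 (percentile 21.8) and neural and glial markers 0.00 (percentile 90.6, and 98.74 for the mean). Single members of the last 2 passed 2-fold: Lpl, lipoprotein lipase, was 2.32-fold higher and Tubb3, a neuronal tubulin, had values of 4.63 and 5.71.

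RAS-MAPK output genes, which report the pathway downstream of KRAS, had a median of 0.25 (percentile 92.0), inside the random range, while their mean lay at percentile 98.08 and their median at 99.84 without matching on mean value. With the signal trend removed the median was 0.11. Of 20 members, 15 were positive and 2 passed 2-fold: Dusp4, a phosphatase of ERK, was 2.79-fold higher and Phlda1 was 2.43-fold higher. Epha4 and Fosl1 differed by 0.73 and 0.72. Among 7 measured EGFR family ligands (median 0.11, percentile 86.1) Btc, betacellulin, was 2.16-fold higher (a difference of 0.99 after repeated quantile normalization), and Tgfa and Hbegf each differed by 0.16. Stem and progenitor genes had a median of 0.22 (percentile 95.7). This list lay in the upper 2.5% with its mean (99.27), with the signal trend removed (97.78), after repeated quantile normalization (97.86) and without matching (99.13). It included Dclk1, a tuft cell kinase, Abcg2 and Bmi1 at 0.89, 0.84 and 0.59.

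The Notch pathway list had a median of -0.22 (percentile 0.99), with 14 of 20 members negative and none past 2-fold. Dll1 and Jag2, Notch ligands, differed by -0.58 and -0.56, the receptor Notch1 by -0.52 and the target Hes5 by -0.47. The target Hes1 and the transcription factor Rbpj, named after their values were seen, differed by 0.44 and 0.30. Immediate early and heat shock genes had a median of -0.11 (percentile 0.070) and a mean of 0.0020, with 15 of 23 negative; Atf3, Fos and Junb differed by -0.40, -0.39 and -0.39, and Egr2 had values of 4.88 and 6.53. Without matching on mean value this list lay at percentile 20.22, and its median was -0.28 with the signal trend removed. Unfolded protein response genes had a median of -0.05 (percentile 0.92) and a mean of 0.052, so median and mean differ in sign; Asns, Xbp1 and Atf4 differed by 0.97, 0.50 and 0.36 and Dnajb9 by -0.35. The percentile of this last list was 14.60 once the signal trend was removed.

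Cytoskeletal and adhesion lists lay inside their random ranges. Actomyosin cortex genes had a median of 0.16 (percentile 61.4), with none of 37 past 2-fold; Tagln2 (transgelin 2), Myl12a (a myosin regulatory light chain), Rnd3 and Zyx (zyxin) differed by 0.84, 0.76, 0.72 and 0.57. Integrin and basement membrane genes had a median of 0.11 (percentile 65.5), with none of 28 past 2-fold and Itga5, Itga6, Itgav and Hspg2 at 0.83, 0.70, 0.70 and 0.57. YAP and TAZ targets had a median of 0.11 (percentile 70.6); Ankrd1 had values of 4.34 and 5.43 and Ccn1, Rbms3 and Nt5e differed by 0.78, 0.60 and 0.55. NF-kB and cytokine genes had a median of 0.14 (percentile 84.4); the alarmin Il33 was 2.16-fold higher, and Cxcl5, Csf1 and Cxcl2 differed by 0.97, 0.83 and 0.78. Interferon response genes had a median of -0.06 (percentile 15.9), with Rsad2 at -0.69 and Irf7 at 0.60. Genes of the p53 response had a median of 0.10 (percentile 58.2), with Phlda3 higher by 1.02 and Plk2 by 0.74. Once the signal trend was removed, the medians of the integrin, YAP and TAZ, and p53 lists turned negative, to -0.0002, -0.039 and -0.061, the actomyosin median was 0.049, and Il33 and Phlda3 differed by 0.93 and 0.86, under 2-fold.

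**Figure D2:**
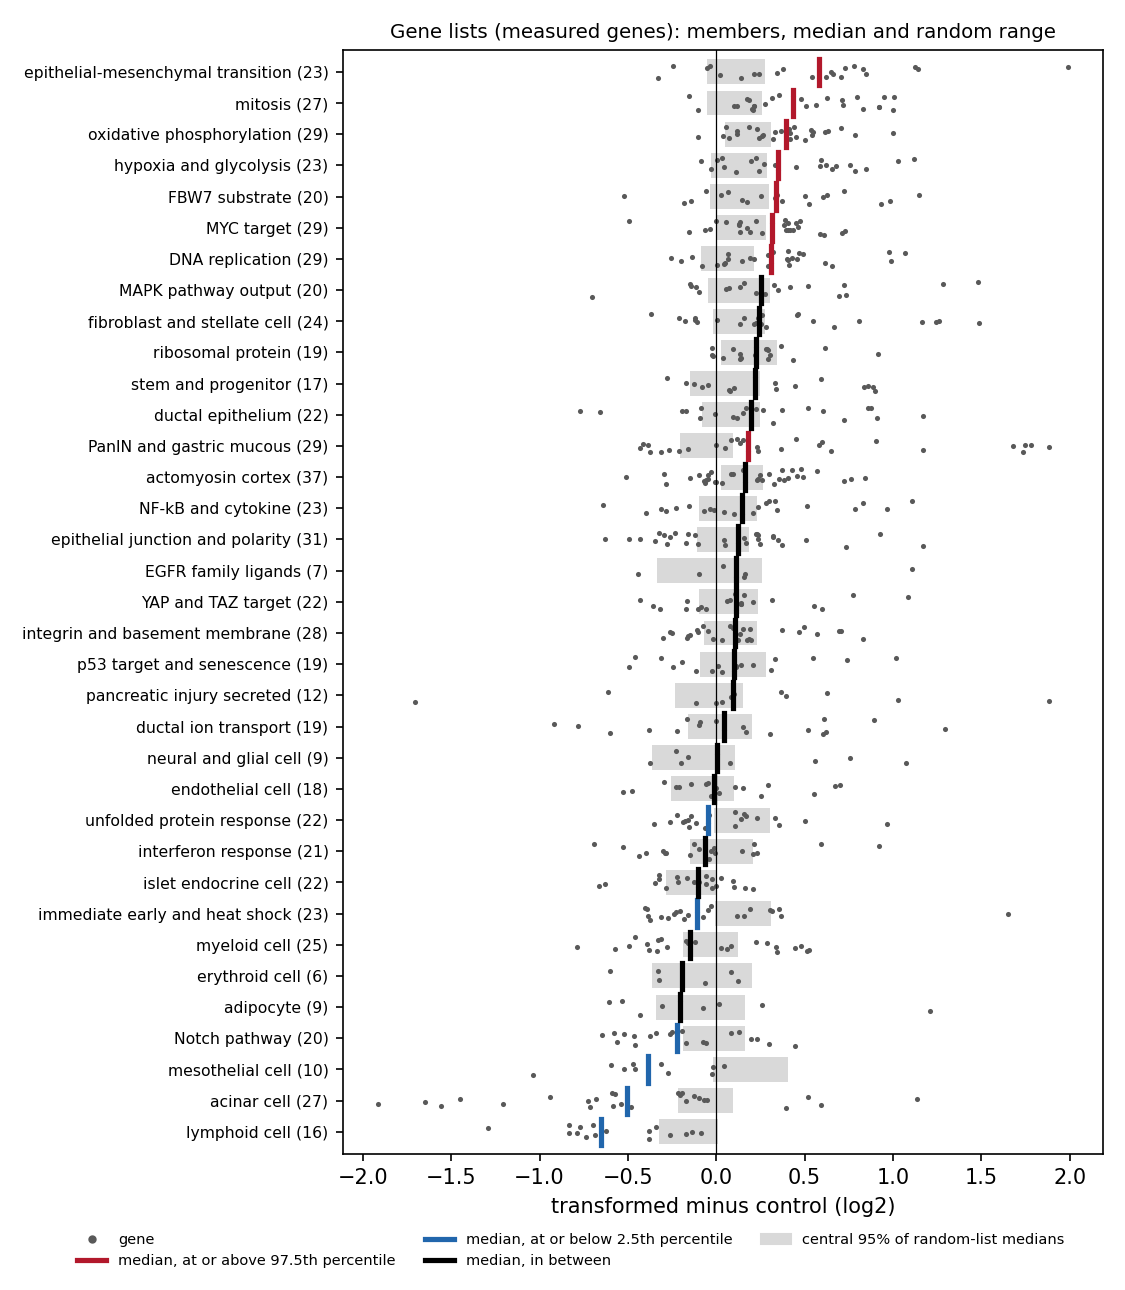
Differences (transformed minus control, log2) of the measured genes of each of the 35 lists, with 1 point per gene, a bar at the list median, and a grey band that leaves out 2.5% on each side of the medians of 10000 random lists matched on mean value. The 8 red medians lie above their bands, from 0.18 for the gastric mucous list to 0.58 for the epithelial-mesenchymal transition list, and the 6 blue medians lie below theirs, down to -0.65 for lymphoid markers.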

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

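Probe sets without a gene symbol, and those with several, entered no comparison and held differences of their own. Among the 12146 probe sets with no symbol, 354 past the floor were at least 2-fold higher in the transformed array and 413 at least 2-fold lower, with extremes of 4.31 and -4.05. Among the 19938 named genes these counts were 218 and 42. Probe sets without a symbol thus passed 2-fold at a higher share and without an excess of higher values. Among the 1621 probe sets with several symbols, 23 were at least 2-fold higher and 14 at least 2-fold lower, with extremes of 1.61 and -3.12. Whether these probe sets measure transcripts above background was not assessed, and no biological explanation of their differences was tested.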

How the results depend on the processing

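With 1 array per group, no replicate could be left out. No paired analysis was possible because each group has 1 array. Protein-coding genes only and matching on gene span were chosen after seeing the data. The count of genes at least 2-fold higher was 218 and lay between 146 and 243 under the alternatives run. The count of lower genes was 42, and it was 83 with no floor on dim genes (73.7% of calls higher, against 83.8%), 17 with the floor at the 75th percentile and between 31 and 49 otherwise. Removal of the signal trend kept 149 of the 218 higher and 32 of the 42 lower genes, and repeated quantile normalization kept 144 and 35. Of 56 named genes past 2-fold, 47 remained past it without the trend and 45 after quantile normalization, and Myc went from 1.15 to 0.97 and 0.98. List percentiles kept their side of the limits in 315 comparisons and crossed them in the others. Of the 315, 35 came from centring, which moved every list median by 0.029 and could change no percentile. List medians shifted by less than the standard deviation of random lists in 211 comparisons and by more in 63. Of the 211, 35 came from centring and were fixed in the same way. A median that stood apart changed sign in 3 comparisons. These values follow, and their cause was not tested. With members under the floor left out, list values became acinar -0.58, islet 0.00, endothelial 0.085, injury protein 0.38 and ductal ion transport 0.17. With members under the floor left out, percentiles became myeloid 1.68 and gastric mucous 96.38. With means in place of medians, list values became myeloid -0.064, lymphoid -0.56, fibroblast 0.37, neural 0.17, adipocyte -0.075, gastric mucous 0.42, unfolded protein 0.052 and immediate early 0.0020. With means in place of medians, percentiles became fibroblast 99.88, neural 98.74, MAPK 98.08, MYC target 95.59, injury protein 98.08, unfolded protein 9.11 and stem 99.27. Without matching on mean value, percentiles became ductal 99.35, fibroblast 99.94, MAPK 99.84, junction 98.17, actomyosin 99.70, NF-kB 97.86, unfolded protein 48.86, immediate early 20.22 and stem 99.13. Others became ribosomal protein 99.47. With the signal trend removed, list values became ductal 0.11, acinar -0.37, islet 0.069, lymphoid -0.46, fibroblast 0.049, endothelial 0.089, mesothelial -0.58, neural 0.18 and MAPK 0.11. Others became FBW7 substrate 0.16, MYC target 0.13, mitosis 0.31, DNA replication 0.21, gastric mucous 0.27, injury protein 0.21, epithelial-mesenchymal 0.46, junction 0.045 and actomyosin 0.049. Further values became integrin -0.0002, YAP and TAZ -0.039, hypoxia 0.26, oxidative phosphorylation 0.20, immediate early -0.28, p53 -0.061 and ribosomal protein 0.031. With the signal trend removed, percentiles became FBW7 substrate 96.27, MYC target 96.55, injury protein 98.88, unfolded protein 14.60 and stem 97.78. After repeated quantile normalization, list values became ductal 0.092, acinar -0.40, islet 0.049, lymphoid -0.47, fibroblast 0.049, endothelial 0.081, mesothelial -0.62, neural 0.18 and MAPK 0.11. Others became FBW7 substrate 0.16, MYC target 0.13, mitosis 0.29, DNA replication 0.21, gastric mucous 0.27, injury protein 0.21, epithelial-mesenchymal 0.44, junction 0.045 and actomyosin 0.026. Further values became integrin -0.0096, YAP and TAZ -0.058, hypoxia 0.25, oxidative phosphorylation 0.18, immediate early -0.31, p53 -0.083 and ribosomal protein 0.039. After repeated quantile normalization, percentiles became FBW7 substrate 97.35, injury protein 98.85, unfolded protein 10.71 and stem 97.86. Without genes of several probe sets, list values became actomyosin 0.23, unfolded protein 0.029 and ribosomal protein 0.14. Without genes of several probe sets, percentiles became ductal 97.50, hypoxia 97.47 and unfolded protein 9.30. With matching on gene span, percentiles became MYC target 96.15. The mitosis, DNA replication, oxidative phosphorylation and epithelial-mesenchymal transition lists stayed in the upper 2.5% of random lists, and the acinar, lymphoid, mesothelial and Notch lists in the lower 2.5%, under each alternative that gave them a value. Signal over background was not assessed, which limits statements about dim genes.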

Other observations

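After the data were seen, 16 further gene groups were looked at. Of these, 10 lay in the upper 2.5% of matched random lists, counting zinc finger genes at its limit, and 0 in the lower 2.5%. The groups were chosen with the values known, so this count cannot be set against chance. The histone groups overlap, as do the NADH dehydrogenase group and the oxidative phosphorylation list. Replication-dependent histone genes had the largest median, 0.61, with 20 of 23 members positive. Beside H2ac4, H2bc14 was 3.11-fold, H4c4 2.60-fold and H2ac15 2.29-fold higher, H2bc3 had values of 5.18 in the control and 6.42 in the transformed pool, and these genes have near-identical copies, so single values are uncertain. A wider histone pattern of 30 genes had a median of 0.46. Mitochondrial ribosome genes had a median of 0.31, with 64 of 77 positive. Mitochondrial import genes had a median of 0.36 over 24 members, with Timm50, Tomm22 and Timm17a 2.74-fold, 2.67-fold and 2.40-fold higher. NADH dehydrogenase genes had a median of 0.37, with 40 of 43 positive and Ndufs5 3.42-fold higher. Proteasome subunits had a median of 0.36, with 33 of 39 positive and Psmd10 2.01-fold higher. The random medians were 0.14 (mitochondrial ribosome), 0.12 (import), 0.17 (NADH dehydrogenase) and 0.16 (proteasome). That part of each median is shared with genes of like signal. Values without the signal trend were not computed for the 16 groups.

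Glutathione enzymes had a median of 0.27 over 34 members, with Gstm5 3.01-fold and Gpx7 2.23-fold higher. S100 proteins had a median of 0.40 over 14 members against a random median of 0.095, with S100a10 2.07-fold higher. Matrix metalloproteinases and their inhibitors had a median of 0.08, with Timp1 2.73-fold higher. Zinc finger genes (347 measured) had a median of 0.00 against a random median of -0.05. That median lay at the upper limit of the random range (0.00), and its percentile of 97.64 counts equal random medians in part. The other groups lay inside their ranges: cholesterol synthesis (median 0.14), RNA polymerase (0.16), small nucleolar RNA (-0.02), keratins (-0.15), semaphorins and plexins (-0.11) and mast cell genes (-0.08). The genes of these groups, apart from H2ac4, were named after their values were seen.

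Both pools came from the same mice by their labels. Xist, expressed from the inactive X chromosome, was 9.78 in the control and 9.66 in the transformed pool, and the Y-linked Eif2s3y was 2.34 in both. Among mesothelial markers, Upk1b was 11.49 in the control and 11.03 in the transformed pool, Upk3b 11.30 and 10.99, and Wt1 10.41 and 10.46. Values of different probe sets depend on their probes, so these levels give no share of cells. These 5 genes were named after their values were seen.

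In the patterns that follow, the tests of gene span and of the signal trend in the programme lists were set before their results were seen, and the tests of the lower cell type lists and of mast cells were chosen afterwards.

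The first pattern is the set of 8 programme lists with medians above their random ranges. The tables argue against gene span as the whole cause, since 7 of the 8 lists, without MYC targets (percentile 96.15), stayed above after matching on span. For MYC targets gene span stays open, since the random lists matched on span also used 10 bins of mean value in place of 20. Across 11076 protein-coding genes past the floor, gene span and difference had a Spearman rho of -0.029. With an intensity-dependent trend between the 2 arrays removed 6 of the 8 stayed above. The lists had been picked against random lists of like mean value, which fixes most of that count. Medians of these 6 then ran from 0.20 (oxidative phosphorylation) to 0.46 (epithelial-mesenchymal transition). The same choice of lists favours positive medians here, so these values do not decide about the trend. The median of the gastric mucous list rose from 0.18 to 0.27, and for the others the trend stays open. It also stays open for FBW7 substrates and MYC targets, at 0.16 and 0.13 without it. A difference between the pools in RNA amount or quality, or in their mix of cell types, was not tested. These are confounded with the CD44 sort, as is a biological difference of the transformed cells.

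The second pattern is the lower acinar, lymphoid and mesothelial lists in the transformed pool. Whether the control pool held a larger share of all other cell types was not decided. The low values did not extend to all other cell type lists, although myeloid markers past the floor were also low (percentile 1.68). The fibroblast and mesothelial lists were set against each other after their values were seen, so their distance cannot decide it. Fibroblast markers also share the mesenchymal character of the higher epithelial-mesenchymal transition list. Relative to random lists the fibroblast list stood at 0.12 and the mesothelial list at -0.57, a distance of 0.69 against a standard deviation of 0.13 between random lists. With an intensity-dependent trend between the 2 arrays removed 3 of the 3 lists stayed below, but they too had been picked against random lists of like mean value. The trend raises bright genes, and the mesothelial list was bright, with a median of 10.58 in the control. Its median difference went from -0.39 to -0.58 once the trend was removed, which argues against the trend for this list. For the acinar and lymphoid lists, at -0.37 and -0.46 without it, the trend stays open as a part of the difference. A changed share of single cell types, and lower expression within the sorted cells, stay open as untested. A pure YFP gate would remove lymphocytes and other cells without Cre activity, but the purity of the sort was not assessed. Of 25 myeloid markers, 15 were past the expression floor. Whether the gate left mesothelial cells, which are known to express keratin 19, was not determined.

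The third pattern is the height of Mcpt2 and Mcpt1 in the transformed pool. Mast cells in the CD44-positive pool, which a pure YFP gate would remove, cannot be told apart from other sources. The 13 other mast cell genes measured had a median difference of -0.08 (-0.0832), but 2 of them were past the expression floor, and those, Tpsab1 and Hdc, were higher by 0.78 and 0.62. Cpa3, an abundant mast cell protease, was 3.92 in the control and 3.43 in the transformed pool, under the floor, and these 3 genes were named after their values were seen. Signal shared between the probe sets of Mcpt1 and Mcpt2 also stays open.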
